A study of Homo sapiens with 10 samples.

How the data were processed

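Peak lists were analysed for 10 samples of MCF-7 cells treated with 17β-estradiol: 3 ERα ChIA-PET samples, of which 2 are sequencing runs of replicate 1, 1 ERα ChIP-PET sample, 1 IgG ChIA-PET sample, 2 H3K4me3 ChIP-Seq libraries and 3 RNAPII ChIP-Seq libraries. Per the labels, 3 samples were sequenced on the 454 platform and 7 on Illumina. Per the labels' protocols, cells were depleted of hormone for at least 72 h in medium with 5% stripped serum, treated with 100 nM estradiol for 45 min, crosslinked with 1% formaldehyde and sonicated before immunoprecipitation. The aligner, peak caller, thresholds and genome build are not given in the sources used here.

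The 15 deposited files have no header. The ChIA-PET and ChIP-PET files give a chromosome, a start, an end and a whole number per peak; the ChIP-Seq files give a chromosome, a single position and a whole number. The authors deposited this whole number as a score per peak, called the height here. What it counts is not stated, so it was used to rank, describe and test peaks within a list. Across lists it entered the planned correlation of heights at sites shared by the ERα replicates. The joined H3K4me3 list was also cut at a single median height over both libraries to give its higher part. Coordinates were taken as the files give them. The depth of the libraries is unknown, and a confidence interval here covers the counting error over the listed peaks only.

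Peaks were called by the authors per list. One list stood unchanged under both the 454 and the Illumina sample of replicate 1 and was used once, as the replicate 1 list. A list of its own was used for replicate 2. Of the lists of replicate 1 that stood under only 1 of the platforms, those of 2725 and 3430 peaks were used for the platform comparison. How the lists of a sample differ is not stated. The remaining lists, of 164, 4008 and 37 peaks, entered only as alternatives. The 3 RNAPII files hold identical values and were used once, since the labels say that the libraries were merged. The labels also speak of merging for H3K4me3, but its 2 files differ. They were joined by adding the 6364 library 1 positions with no library 2 position within 1 kb to library 2. The labels name the ERα ChIA-PET replicates as biological replicates; nothing says that the ChIP-Seq libraries came from separate cultures.

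A site counted as shared when it overlapped a site of the other list by at least 1 bp. This was set before the data were examined for all lists. Since the H3K4me3 and RNAPII files hold single positions, a distance of at most 1 kb was used for them instead, a change made after the files were seen, and 1 bp overlap became an alternative. The chance share was the mean over 1000 circular shifts of one list within each chromosome, with a one-sided permutation p whose smallest value is 0.001. Differences of median height and correlations were tested two-sided with 100000 resamples, whose smallest p is 1e-05. Shares of marked sites were compared with Fisher's exact test. Confidence intervals are exact (Clopper-Pearson, 95%). Families of tests were adjusted by the Benjamini-Hochberg method, and the threshold was 0.05. Density per chromosome used the largest coordinate in any list as the length. The densest bins are the 1% of 1 Mb bins (29 of 2875) with the most sites of both replicates together. Clustering was tested against 1000 uniform random placements.

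The sites named are the 10 highest of each ERα replicate shared with the other, the 5 highest of the H3K4me3 and RNAPII lists, all IgG peaks and the 3 bins of 1 Mb with the most sites per replicate. Gene names were to be assigned only from an annotation of the files' build. The gene tables used here are for GRCh38, and 2522 peaks on 10 chromosomes lie beyond the last gene end in them, so the files follow another build. The planned test of genes near ERα sites, with its gene lists and windows, was therefore not run, and no gene is named. Paired-end links between sites were not analysed here.

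The alternatives were an overlap of 50% of the smaller peak, a distance of 1 kb, the part of each list above its median height, uniform placement, the densest bins left out, each ERα replicate or H3K4me3 library left out, the other lists of a sample, and distances of 10 and 200 kb for clustering. Moves of each site by 20 to 100 kb were added after the data were seen. The overlap code was tested on simulated lists of 8000 sites with a planted share of 30% and gave 30%, and 4 of 100 unrelated pairs of simulated lists gave a p under 0.05. The simulated sites were placed uniformly, without the clustering and shared dense regions of the real lists. The error rate of the shift test on lists like the real ones is therefore not known from this. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.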

Results

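The data described where estrogen receptor alpha (ERα), a hormone-activated transcription factor, was bound to chromatin in MCF-7 cells. MCF-7 is an estrogen-responsive human breast cancer line whose genome carries amplified segments. The cells had been kept in hormone-free medium for at least 72 h and then received 100 nM of 17β-estradiol for 45 min. There was no untreated group among the 10 samples, so no comparison addressed the effect of estradiol. ERα ChIA-PET, which joins the ends of chromatin fragments held in one immunoprecipitated complex before paired-end sequencing, was represented by 2 biological replicates. Replicate 1 had been sequenced on both the 454 and the Illumina platform and was counted once. An ERα ChIP-PET library and a mock ChIA-PET library made with IgG served as controls. Both controls were sequenced on 454 only, while replicate 2 and the ChIP-Seq libraries were sequenced on Illumina. ChIP-Seq of H3K4me3, a histone mark of active promoters, came from 2 libraries, and ChIP-Seq of RNA polymerase II (RNAPII) from 3 libraries merged into 1 list. The values were the positions and heights of called peaks. The number of reads behind each list is unknown, so numbers of peaks were not compared between lists by a test.

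ERα ChIA-PET gave 14703 sites in replicate 1, with a median height of 7 and a median width of 56 bp. Replicate 2 gave 6888 sites, with a median height of 8 and a median width of 30 bp. The ChIP-PET control gave 1256 sites with a median height of 6. The IgG mock library gave 2 peaks, on chromosome 1 at 121186273 to 121186292 with a height of 11 and on chromosome 6 at 58886115 to 58886283 with a height of 9. Neither shared a base with a site of the ERα ChIA-PET replicates, but both lay within 1 kb of a site in each of them. Both also lay within 1 kb of a ChIP-PET site, of an RNAPII position and of a position in each H3K4me3 library. Near the chromosome 1 peak, the ChIP-PET site had a height of 153, the greatest in its list. A replicate 2 site there had 257 and an H3K4me3 library 2 position 482. Near the chromosome 6 peak the heights were 75 in ChIP-PET, 55 in replicate 2 and 534 in H3K4me3 library 2. A peak at these 2 places was thus not particular to the ERα antibody. The H3K4me3 libraries gave 37542 and 72933 positions, and RNAPII gave 13133. Heights were the authors' own peak scores. They were ranked and tested within a list, except for a correlation of the heights of sites shared by the ERα replicates. A further exception was the higher part of the joined H3K4me3 list, cut at a single median height of 14 over both libraries. The median height was 7 in library 1 and 15 in library 2, so this cut favoured library 2. Levels of height are not comparable between lists.

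The agreement of the ERα replicates was examined first. Of the replicate 1 sites, 2272 shared at least 1 bp with a replicate 2 site, or 15.5% (exact 95% confidence interval 14.9 to 16.1%), against a mean of 0.0308% after random circular shifts along the chromosomes. In the other direction 33.0% of replicate 2 sites were shared (31.9 to 34.1%), against 0.0655%. The same number of sites, 2272, was shared in each direction. Replicate 1 had 14703 sites and replicate 2 had 6888, so with 1 partner per site most replicate 1 sites could not be shared. Both shares exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest these can give). Moves of each site by 20 to 100 kb gave a chance of 0.122% and 0.258%. When a site within 1 kb was accepted, the shares were 30.6% and 66.1%. Outside the 1% of 1 Mb bins with the most ERα sites, the 1 bp shares were 15.5% and 38.1%. Sites inside these bins thus lowered the replicate 2 share. With the lists given only with the 454 or the Illumina sample as replicate 1, 40.2% and 36.7% of their sites shared a base with replicate 2.

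High sites had a site of the other replicate within 1 kb more often than low ones. Within 1 kb, replicate 2 held 13.3% of the replicate 1 sites with heights of 4 to 5, 19.97% of those with 6 to 7, 31.2% of those with 8 to 14 and 65.7% of those with 15 or more. Replicate 1 held 44.9%, 61.6%, 77.0% and 91.8% of the replicate 2 sites in the successive quartiles of height. By 1 bp overlap the replicate 2 shares were 24.8%, 35.4%, 41.7% and 35.8%, so the highest quartile lay below the one before it. By 1 bp overlap, sites found in the other replicate had a median height of 12 against 6 in replicate 1, and of 9 against 7 in replicate 2 (two-sided permutation test, p = 1e-05 for each, the smallest possible). High sites were narrower: the median width was 107 bp in the lowest quartile of replicate 1 and 15 bp in the highest. In that highest quartile 27.2% of sites shared a base with replicate 2, which is 38.6 percentage points under the share within 1 kb, and in the lowest quartile the gap was 5.32 points. Across the 2272 shared sites, which are not independent replicates, the heights in the 2 lists were correlated with a Spearman rho of 0.351 and a Pearson r of 0.43 on the log2 scale (permutation p = 1e-05 for each).

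**Figure D1:**
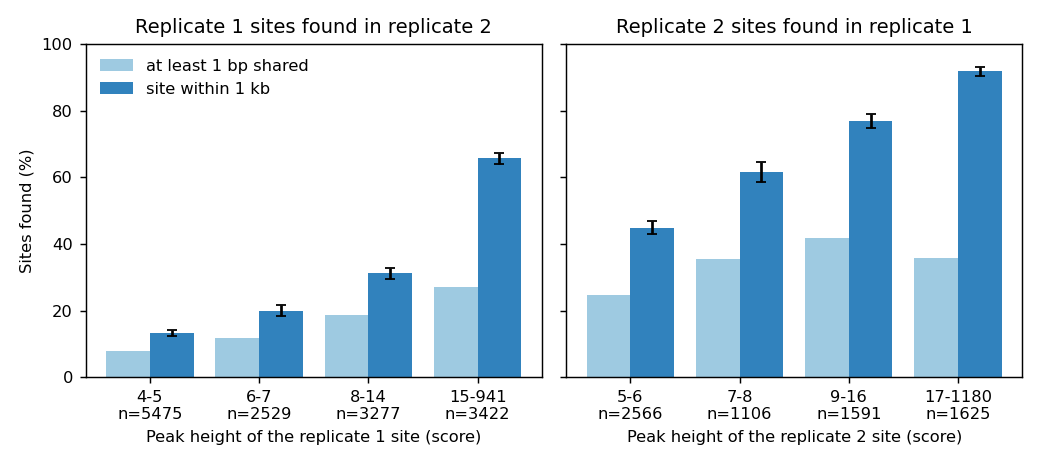
Share of ERα ChIA-PET sites of one replicate (y axis, %) found in the other, by quartile of peak height (x axis, score, with the number of sites). Light bars need at least 1 shared bp and dark bars a site within 1 kb, with exact 95% confidence intervals; the dark bars rise to 65.7% for replicate 1 and 91.8% for replicate 2.

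Individual sites were named by a rule set before the data were examined: the 10 highest of each replicate that shared a base with the other. Coordinates are those of the files, whose genome build is not given in the sources used here, so no gene was assigned. Of these, 3 sites stood in both lists of 10. They lay on chromosome 10 at 117414379 to 117414387 (height 289 in replicate 1 and 195 in replicate 2), on chromosome 20 at 52177259 to 52177261 (242 and 293) and on chromosome 15 at 69184293 to 69184296 (186 and 165). The highest named site of replicate 2 lay on chromosome 17 at 54072208, with a height of 1180 there and 143 in replicate 1. Of each list of 10, 9 had a ChIP-PET site within 1 kb. An H3K4me3 position lay within 1 kb of 7 named sites of replicate 1 and of 9 of replicate 2, and an RNAPII position within 1 kb of 5 and 4. Because high sites were narrow, the rule passed over most of the highest peaks. The 10 highest of replicate 1 all had a replicate 2 site within 1 kb, but 0 of the 10 shared a base with one, and in replicate 2 the numbers were 10 and 1. The highest site of replicate 1, chosen after its values were seen, lay on chromosome 17 at 57155525 with a height of 941, at 37 bp from a replicate 2 site with a height of 320.

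Lists given with only 1 of the 2 sequencing platforms were compared within replicate 1. How these lists were made is not stated, so their shares need not measure the agreement of complete runs. The list given only with the 454 sample held 2725 sites, of which 46.3% (44.4 to 48.2%) shared a base with the 3430 sites given only with the Illumina sample. In the other direction the share was 36.8% (35.2 to 38.4%). The shifted lists gave 0.0272% and 0.0225% (one-sided permutation p = 0.001 for both), and the local moves 0.0866% and 0.0691%. Within 1 kb the shares were 67.8% and 53.9%.

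The ChIP-PET control shows how far sites called without the ligation step of ChIA-PET coincide with those called with it. Of the 1256 ChIP-PET sites, 34.4% (31.8 to 37.1%) shared a base with replicate 1 and 30.6% (28.0 to 33.2%) with replicate 2, against 0.110% and 0.0638% after shifts (one-sided permutation p = 0.001 for both). Moves of each site by 20 to 100 kb, which keep the regional density, gave a chance of 0.724% and 1.18%, so that the folds over chance fell from 312 and 479 to 47.5 and 26.0. Within 1 kb the shares rose to 72.1% and 71.9%. Outside the 1% of 1 Mb bins with the most ERα sites, 751 ChIP-PET sites remained, of which 48.6% and 42.9% shared a base. The 505 ChIP-PET sites inside these bins therefore lowered the shares over all sites.

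ERα sites were then set beside the promoter mark. In replicate 1, 41.5% of sites (40.7 to 42.3%) lay within 1 kb of an H3K4me3 position, against 5.15% after circular shifts, and in replicate 2 48.2% (47.0 to 49.3%) did, against 5.88%. The mean of the replicates was 44.8% ± 4.73 (SD, n = 2), and both exceeded all shifts (one-sided permutation p = 0.001). The median distance from an ERα site to the nearest H3K4me3 position was 3.48 kb in replicate 1 and 1.27 kb in replicate 2, and 37.8% and 31.7% of sites lay over 10 kb away. The shares rested on the larger H3K4me3 library: without H3K4me3 library 2 they were 11.4% and 21.6%, against 2.52% and 2.99% after circular shifts (folds of 4.5 and 7.2). With the higher part of each list, above its median height, they were 22.0% and 23.01%, against 2.41% and 2.56% (folds of 9.13 and 8.97). When each site was moved by only 20 to 100 kb, which keeps the regional density, chance rose to 10.4% and 20.6%, which leaves folds of 3.99 and 2.34 in place of 8.05 and 8.19.

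The RNAPII list was shorter than that of H3K4me3, so the shares near the 2 marks are not directly comparable. The share of ERα sites within 1 kb of an RNAPII position was 9.55% (9.08 to 10.04%) in replicate 1 and 20.5% (19.5 to 21.5%) in replicate 2, against 0.963% and 1.29% after circular shifts (one-sided permutation p = 0.001 for both). The mean was 15.02% ± 7.73 (SD, n = 2). The median distance to the nearest RNAPII position was 93.5 kb and 54.7 kb. Outside the 1% of 1 Mb bins with the most ERα sites, the shares were 6.69% and 9.13%, against 0.67% and 0.69% after circular shifts (folds of 9.99 and 13.2). With the higher part of each list they were 6.09% and 9.30%, against 0.466% and 0.50% (folds of 13.1 and 18.6). With the local moves, chance was 3.64% and 11.7%, and the folds fell from 9.92 and 15.9 to 2.62 and 1.76.

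**Figure D2:**
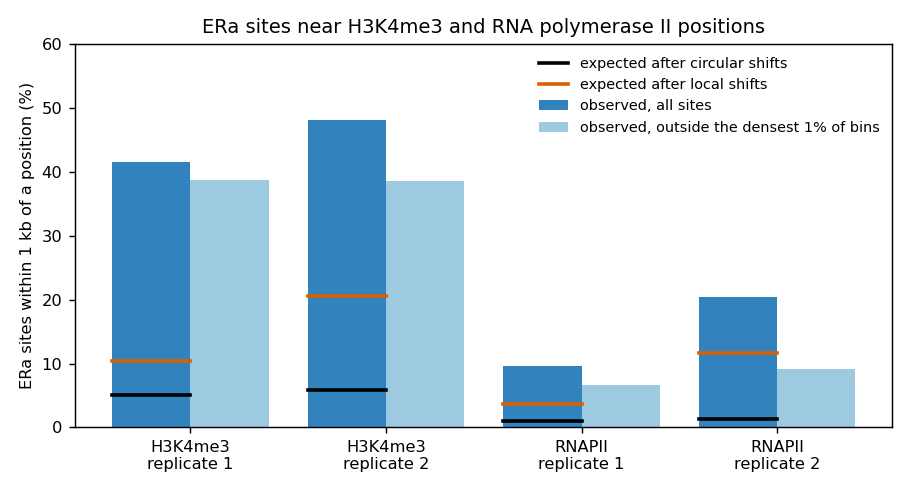
Share of ERα ChIA-PET sites (y axis, %) within 1 kb of an H3K4me3 or RNAPII position, per mark and replicate (x axis). Dark bars hold all sites and light bars those outside the densest 1% of 1 Mb bins; black lines mark the mean after circular shifts and orange lines the mean after moves of 20 to 100 kb. The lines belong to the dark bars. The RNAPII share of replicate 2 is 20.5% in all bins and 9.13% outside the densest, against means after circular shifts of 1.29% and 0.69%.

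H3K4me3 and RNAPII were also compared with each other. Of the RNAPII positions, 83.5% (82.8 to 84.1%) lay within 1 kb of an H3K4me3 position, against 6.57% after shifts, and 17.1% of the 79297 H3K4me3 positions of both libraries lay within 1 kb of RNAPII, against 1.12%. Taking only H3K4me3 positions seen in both libraries raised the last share to 34.1%, and library 1 alone gave 29.1%. Of the library 1 positions, 83.1% lay within 1 kb of a library 2 position, and 44.1% the other way, against 5.43% and 2.83%. Each of these 4 shares exceeded all shifts (one-sided permutation p = 0.001). With the local moves, chance was 27.3% for RNAPII near H3K4me3 and 5.09% the other way, which lowers the folds from 12.7 and 15.3 to 3.06 and 3.35, and 17.0% and 9.17% between the libraries.

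Most ERα sites had neither mark within 1 kb: 57.9% in replicate 1 and 50.8% in replicate 2. Sites with H3K4me3 alone made up 32.6% and 28.8%, those with RNAPII alone 0.680% and 1.07%, and those with both 8.87% and 19.4%. H3K4me3 here means a position of either library, which lay near 41.5% and 48.2% of sites. Positions found in both libraries lay near only 11.55% and 22.01%, and the classes were not rerun with these. In replicate 1 the median height was 6 without a mark and 8 in each of the other 3 classes (permutation test with Benjamini-Hochberg adjustment over 6 comparisons, adjusted p = 2e-05 for H3K4me3 alone, 0.028 for RNAPII alone and 2e-05 for both). At 1 bp overlap, the rule set first, these differences turned to -2, -2 and -3, of which only that for H3K4me3 alone passed the test (adjusted permutation p = 0.003, 0.089 and 0.19). In replicate 2 it was 8 without a mark and 6 with both (adjusted permutation p = 2e-05), while 9 with H3K4me3 alone and 8 with RNAPII alone did not pass the test (adjusted p = 1 for each). Outside the densest bins the replicate 2 difference turned round, to a median height of 12 with both marks against 8 without (adjusted permutation p = 2e-05), and sites with H3K4me3 alone were 2 higher than unmarked ones (adjusted permutation p = 4e-05). Most replicate 2 sites with both marks lay in these bins: 464 of 1337 lay outside, against 3380 of 3497 unmarked sites. Replicate 2 sites had a median height of 6 inside these bins and 9 elsewhere.

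Sites shared by the replicates were compared with those of replicate 1 alone. H3K4me3 lay near 42.6% of the 2272 shared sites and 41.3% of the other 12431 (Fisher's exact test, two-sided, odds ratio 1.06, p = 0.23). RNAPII lay near 11.3% and 9.24% (Fisher's exact test, odds ratio 1.25, p = 0.003). Within the quartiles of replicate 1 height, the RNAPII odds ratio ran from 0.987 to 1.31 and passed the threshold in none, and that of H3K4me3 turned round to 0.762 to 0.978. With sharing taken within 1 kb, the odds ratios were 1.66 for H3K4me3 and 2.75 for RNAPII (Fisher's exact p = 1e-44 and 6e-70). This 1 kb version was not split by height, although sharing within 1 kb and nearness to H3K4me3 both rose with height in replicate 1. Fisher's test treats sites as independent, whereas 67.8% of replicate 1 sites had another within 50 kb, so its p-values may be too small.

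Sites were unevenly spread over the chromosomes. Chromosome 20 had the highest density in both replicates, with 10.7 sites per Mb in replicate 1 and 11.7 in replicate 2, followed by chromosome 17 with 8.43 and 7.36. The lowest autosomal densities were 3.02 on chromosome 18 in replicate 1 and 1.17 on chromosome 13 in replicate 2. Chromosome X had 2.27 and 0.660, and chromosome Y, with 15 and 18 sites but 0 H3K4me3 and 0 RNAPII positions, had 0.261 and 0.314. Over the 24 chromosomes the replicates' densities had a Pearson r of 0.884 and a Spearman rho of 0.876 (permutation p = 1e-05 for both, adjusted over 15 relations 1e-05 and 2e-05). Without the 2 chromosomes farthest from the median, r was 0.858, and over the 22 autosomes r was 0.934 and rho 0.84. Replicate 2 densities also followed those of RNAPII, with r = 0.985 and rho = 0.849 (adjusted permutation p = 1e-05 and 2e-05); r was 0.837 without the 2 chromosomes farthest from the median and 0.884 outside the densest bins. Without these bins, chromosome 20 held 5.35 and 2.45 sites per Mb.

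The 3 bins of 1 Mb with the most sites all lay on chromosome 20 for replicate 1, starting at 51000001 (75 sites), 45000001 (71) and 46000001 (63). For replicate 2 they started at 52000001 (210 sites) and 51000001 (148) on chromosome 20 and at 56000001 (122) on chromosome 17. Other lists also had many peaks there: the bin at 52000001 on chromosome 20 also held 94 ChIP-PET sites, 773 H3K4me3 positions of library 2 and 455 RNAPII positions, against means over all bins of 0.437, 25.4 and 4.57. The IgG library had 0 peaks in any of these bins, but only 2 in all. The 29 densest bins, of 2875 holding any peak, contained 6.85% of replicate 1 sites, 19.1% of replicate 2 sites, 40.2% of ChIP-PET sites and 23.8% of RNAPII positions. The shares of the replicates are raised by the choice of these bins by their sites.

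**Figure D3:**
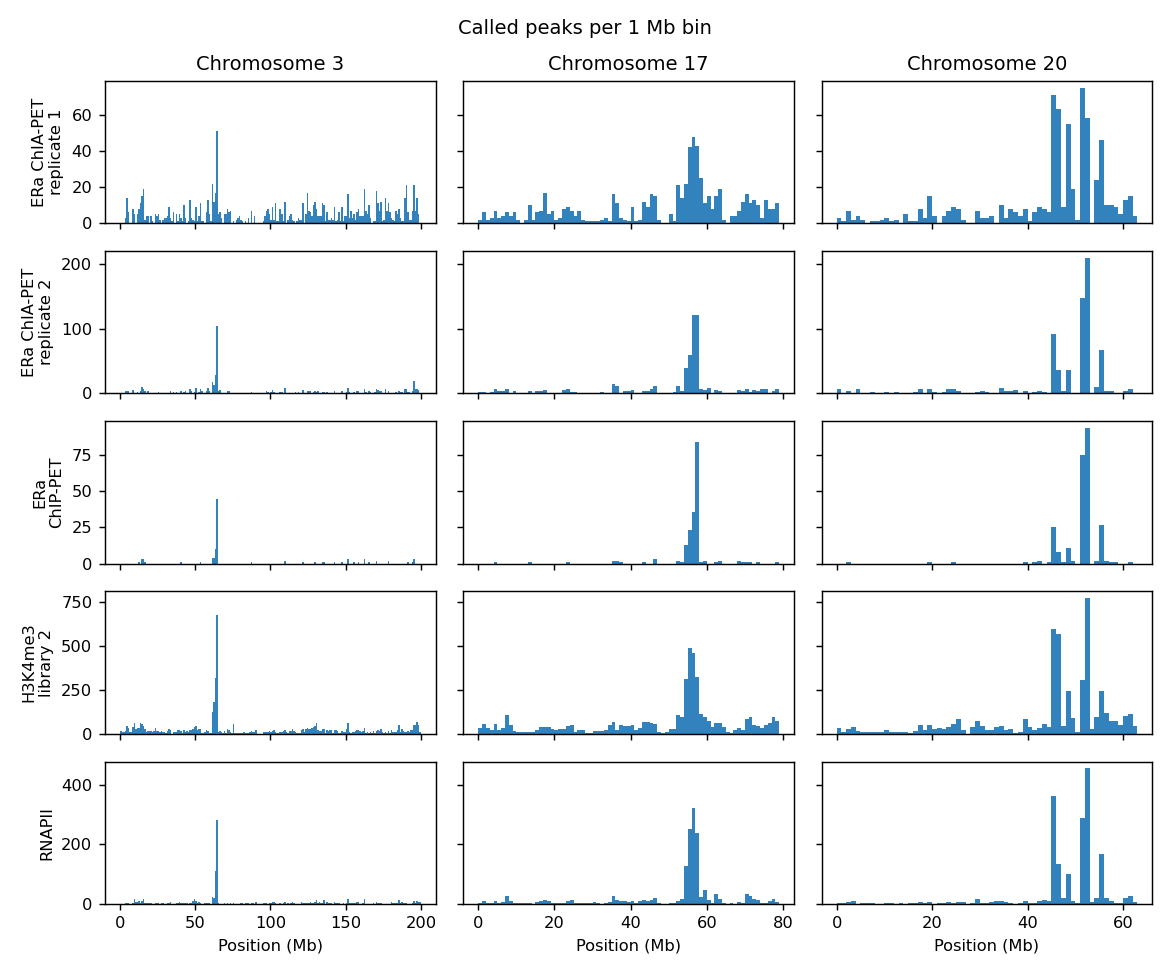
Number of called peaks per 1 Mb bin (y axes, a separate scale per list) along chromosomes 3, 17 and 20 (x axes, Mb) for 5 lists. The bin at 52 Mb on chromosome 20 holds 58 sites of replicate 1, 210 of replicate 2 and 455 RNAPII positions.

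ERα sites lay in groups. Another site of the same list was found within 50 kb of 67.8% of replicate 1 sites and 57.7% of replicate 2 sites, against 40.04% and 26.7% after uniform random placement within chromosomes (one-sided permutation p = 0.001 for both). Without the densest bins the shares were 65.8% against 37.2% and 48.7% against 17.6%. Over all sites, the shares within 10 kb were 36.8% against 9.89% and 36.9% against 6.63%, and within 200 kb 90.8% against 85.6% and 79.8% against 63.3%.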

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

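The bounds of the tests in this part were written before their values were computed, from patterns already seen in the lists, but the split of the dense bins by chromosome and the 3 single bins were chosen after the values were seen. No biological explanation was tested, since all samples had the same treatment.

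Peak lists outside the main comparisons held 164 peaks (a short Illumina list of replicate 1), 4008 peaks and 37 peaks (an intermediate and a short list of replicate 2), above the 2 peaks of the IgG library, which is what singled them out. Depths are unknown, so these numbers are not comparable as signal. Within 1 kb of the main list of the same replicate lay 98.2%, 99.95% and 100% of them.

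The RNAPII list was deposited under a name that speaks of the estrogen receptor. A list of ERα sites was predicted to have at least 50% of its positions within 1 kb of a replicate 1 ERα site, and 12.7% did, under the bound of 25% that argues against this. A list of polymerase near promoters was predicted to have at least 50% within 1 kb of H3K4me3, and 83.5% did. A mislabelled list of some other promoter-bound factor stays open.

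Most replicate 1 sites had no partner in replicate 2. With 1 partner per site this follows from the list lengths, 14703 sites in replicate 1 and 6888 in replicate 2. Leaving out the densest bins changed the share within 1 kb by -1.51 percentage points, but these bins held only 6.85% of replicate 1 sites and could have raised it by at most 2.25 points, so repeat-rich or amplified sequence stays open. Lower depth or a stricter threshold in replicate 2 was predicted to give at least 80% in the highest quartile of height and would be argued against under 50%; the value was 65.7%, so this cannot be told apart from other causes, because the depth of neither list is known.

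Pooled over the 1 Mb bins with the most ERα sites, all lists were denser than elsewhere except IgG, which has too few peaks to tell. For the ERα ChIA-PET lists this follows from the choice of the bins by their sites, so only ChIP-PET, H3K4me3 and RNAPII could have come out otherwise. Raised copy number alone was predicted to make H3K4me3 and RNAPII at least 2 times as dense there, and the lower of their folds was 9.23, so copy number may account for the pooled excess, with gene density and an excess of binding also open. That fold was carried by the 14 bins on chromosomes 3, 17 and 20, where H3K4me3 was 22.5 and 16.8 times as dense in libraries 1 and 2; in the other 15 bins it was 2.24 and 3.10 times. In 3 single bins, picked for that value, both H3K4me3 libraries lay below the mean elsewhere but RNAPII and ChIP-PET lay above it, so they decide nothing. The platform-specific lists held 119.6% of the main list's share in these bins, which decides nothing on repeat-like sequence, since at least 99.5% of their sites lie within 1 kb of the main list.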

How the results depend on the processing

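The local moves, the results without the densest bins for shared sites, the height correlation and the chromosome densities, the 1 kb version of the height comparison and the share of RNAPII positions near ERα were chosen after seeing the data. For 31 results, 167 alternatives were computed: 149 kept their direction and side of the threshold, 10 reversed, 2 kept their side from a difference of 0, 4 lost the threshold and 2 gained it. The 149 include repeats. For lists of single positions, overlap by a part of the smaller peak gave the same shares as 1 bp overlap. Mean shares with an ERα replicate left out are the shares of the remaining replicate, already listed as results. The tally therefore counts more alternatives than there were separate checks. The overlap and clustering results were past the threshold under every alternative run, but their shares moved: replicate 1 sites found in replicate 2 ran from 0.177% with the short replicate 2 list to 61.6% with the short Illumina list, and 1 bp overlap gave 2.16% and 1.61% of ERα sites at H3K4me3. Mean shares without one ERα replicate ran from 41.5 to 48.2% for H3K4me3 and from 9.55 to 20.5% for RNAPII.

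Heights by class depended on the overlap. At 1 bp the replicate 1 differences from unmarked sites became -2 with H3K4me3 alone, -2 with RNAPII alone and -3 with both (adjusted permutation p = 0.003, 0.089 and 0.19). In replicate 2 the difference with H3K4me3 alone, not past the threshold, turned from 1 to -2, that with RNAPII alone went from 0 to -2.5, and that with both stayed -2 but lost the threshold. Wide sites are low and meet a single position by 1 bp more easily, but the cause was not tested. Without the densest bins the replicate 2 difference reversed to 4 with both marks and became 2, past the threshold, with H3K4me3 alone, and 3 with RNAPII alone, not past it. The difference with both marks over all sites thus mixed the low sites of the dense bins, where most such sites lay, with sites elsewhere. Why sites in the dense bins were lower was not tested. The odds ratio of H3K4me3 at shared sites became 1.66 within 1 kb, past the threshold, and 0.791, 0.762, 0.978 and 0.915 in the successive height quartiles (unadjusted exact p = 0.033 and 0.046 in the 2 lowest, adjusted p = 0.11 for both). That of RNAPII became 0.987, 1.09, 1.31 and 1.02 there, none past the threshold, with fewer sites in each quartile; the cause of the reversals was not tested.

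Genes near ERα sites were not run, nor their windows. No paired analysis was possible because the groups share no replicate numbers that pair samples. Unknown depth limits every statement on sites missing from a list.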

Other observations

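The bins, groupings and sites in this part were chosen after seeing the data, and no test was run on them. Of the 29 densest bins, 14 lay on chromosomes 3, 17 and 20, and these held 16.0% of replicate 2 sites, 36.5% of ChIP-PET sites and 21.8% of RNAPII positions. Their density over that of the bins elsewhere was 9.41 times for replicate 1, 40.3 times for replicate 2, 124 times for ChIP-PET and 58.3 times for RNAPII. In the 15 dense bins on other chromosomes the values were 5.17, 7.11, 11.9 and 4.95 times. The dense bins were picked by their number of ERα ChIA-PET sites, which by itself raises the values for both replicates.

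In 3 of the densest bins both H3K4me3 libraries had fewer positions than the mean elsewhere, which was 11.8 in library 1 and 23.3 in library 2, while RNAPII was above its mean elsewhere of 3.52 in each. The bin starting at 15000001 on chromosome 21 held 29 sites of replicate 1 and 19 of replicate 2, with 2 and 7 H3K4me3 positions and 5 RNAPII positions. The bin at 237000001 on chromosome 2 held 26 and 13 sites with 4 and 14 H3K4me3 positions and 9 RNAPII positions, and that at 37000001 on chromosome 8 held 25 and 11 sites with 11 and 18 H3K4me3 positions and 8 RNAPII positions. The chromosome 8 bin lay above the H3K4me3 medians over all bins, 8 in library 1 and 17 in library 2. It was therefore low only against the mean.

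Of the 10 highest peaks of any kind, 7 of replicate 1 and 5 of replicate 2 lay on chromosome 20. The 3 highest RNAPII positions lay close together on chromosome 17, at 54064117, 54091562 and 54111952, with heights of 243, 201 and 125. Each had a replicate 2 ERα site within 1 kb, of height 7, 8 and 6, and none had a replicate 1 site that near; the closest lay at 8090 bp. The next highest RNAPII position, at 121186385 on chromosome 1 with a height of 111, lay 93 bp from an IgG peak. H3K4me3 library 2 had its highest position on chromosome 20 at 55274644, with a height of 702, at the same base as a library 1 position with a height of 330.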
